A study of Homo sapiens with 6 samples.

How the data were processed

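RNA was measured in 6 libraries of HSB-2, a human T-cell leukaemia line. Of these, 3 came from cells resistant to AZD1208, an inhibitor of the PIM kinases, and 3 from naive cells. The resistant cells had been grown in rising concentrations of the drug over 4 months until they kept growing in 1 µM. The labels do not say whether the drug was present at harvest, or whether the libraries of a group came from separate cultures. The titles of the 3 resistant libraries share 1 cell name, so as far as the labels say 1 selected population was compared with naive cells. No time in culture is given for the naive cells. Total RNA was purified with a column kit and sequenced as read pairs on a HiSeq2500.

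Per the submitters' processing notes, reads were demultiplexed with bcl2fastq, trimmed with Trimmomatic 0.32, aligned to GRCh37 with TopHat2 2.0.13 and Bowtie2 2.2.4 and counted with HTSeq, and DESeq2 was then used. The deposited values are raw counts per Ensembl gene, whole numbers whose totals differ between libraries. The annotation release and the strand setting are not stated, so the share of a count that came from an overlapping or antisense gene is unknown. The summary lines of reads given to no gene were left out of library sizes and tests. The counts cover 63677 gene identifiers, of which 52526 were given a symbol by matching to GENCODE v29. That annotation is built on another genome assembly than the counts, and none of its positions is printed. Positions served only to order genes along chromosomes and to find overlapping genes. Overlaps named below are between whole gene spans of that annotation, which may differ from the one used for counting. Of all identifiers, 27369 had at least 1 count.

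Resistant libraries held 28185110, 32490005 and 38537234 counts in genes, and naive libraries 26570834, 27480550 and 24297995. A count of 0 allows up to 3 counts in a library, which is 0.0778 to 0.1235 CPM, the usual unit of counts scaled to library size. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. In the main comparison, genes were kept by edgeR's filterByExpr on the groups, which left 13009. Library sizes were scaled by TMM, and the groups were compared with the robust quasi-likelihood fit and F test of edgeR 4.0.16 in R 4.3.3. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. All log2 fold changes are resistant minus naive, with their standard error (SE), and CPM values are means with the standard deviation (SD) of 3 libraries. A p-value here measures only the spread between these libraries, which may be technical, because no label says that they are separate cultures. Replicate numbers are shared by both groups, but no label says that they mark a shared day or culture, so the libraries were not paired. By deviations from the group means over all genes, the closest naive library of a resistant one had its number in only 1 of 3 cases. Mitochondrially encoded transcripts differed from this, with libraries ranked the same way by number in both groups, and a replicate block was tried as an alternative.

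Gene lists, 39 in number, were drawn up from textbook knowledge of the drug's target, T-cell leukaemia, metabolism, stress, the cell cycle and other cell types. The lists, the tests and the naming rule below were fixed before the data were examined. The 36 lists with at least 3 tested members were compared with all other genes by camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01 between genes. The correlation estimated from the data, and fry, were tried beside it. Within each list, calls were also counted with p adjusted over the list alone. Named genes were the 12 protein-coding genes with the largest rise and the 12 with the largest fall, among called genes with at least 5 CPM on average in the higher group and no overlap between groups. Also named were PIM1, PIM2, PIM3, MYC, LCK, NOTCH1, IL7R and TAL1, whatever their test. A few genes that the rule takes are not reported here. From each list the rule took up to 2 called members per direction with the largest change and at least 2 CPM. Genes named outside this rule are given as further members of a list or are said to have been chosen after their values were seen.

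The procedure was tested on simulated data of the same size in which 200 genes were changed. Of 50 genes per size, edgeR called 20 at 1.25-fold, 39 at 1.5-fold, 40 at 2-fold and 49 at 4-fold, and it called 18 of 12809 unchanged genes. Of the 2-fold genes, it called 39 of 39 with at least 100 counts on average and 1 of 11 below that. The changed genes were drawn evenly over abundance, after a first draw without this had recovered fewer genes at 2-fold than at 1.5-fold and was replaced. Camera called the 1 shifted list and 0 of 35 others. Genes were simulated independently of each other, so this cannot show how often camera calls unshifted lists of correlated genes. Alternatives were median-of-ratios and upper-quartile scaling, scaling without mitochondrial genes, DESeq2 1.42.0, limma-voom, no filter, a filter of 1 CPM in 3 libraries, a replicate block, a test against 1.5-fold (glmTreat) and leaving out each library. A fit with a hypoxia score as a covariate was added after seeing the data. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.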

Results

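The data are RNA sequencing counts from HSB-2 cells, 3 libraries resistant to the PIM kinase inhibitor AZD1208 and 3 naive. Resistant libraries held 28185110 to 38537234 counts in genes and naive libraries 24297995 to 27480550. Reads given to no gene made up 12.595% to 13.103% of each library. The first principal component of log2 CPM held 66.6% of the variance and separated the groups. Pearson's r across genes, which are not independent replicates, was at least 0.994 between resistant libraries and at least 0.9905 between naive ones. It was 0.9744 to 0.984 between the groups.

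The comparison of resistant with naive cells asks which transcripts differ in a population that has come to grow in the drug. In resistant cells the transcripts of oxygen-responsive genes and of glycolysis were lower, with PFKFB4, which makes an activator of glycolysis, 49.0-fold lower and LDHA, the lactate dehydrogenase subunit that favours lactate production, 1.94-fold lower. Stress response genes of the ATF4 list were lower as well, by 1.36-fold at the median. Its member DDIT4, an inhibitor of mTORC1 signalling, fell far more than the list, by 87.2-fold. NF-kB target genes such as TRAF1 and several adhesion and chemokine receptor genes were also lower. MYC, a transcription factor that drives growth, rose 1.54-fold together with genes of ribosome biogenesis, and NOTCH1 and its targets HES1 and PTCRA rose. The calls of these lists by camera were each lost with an estimated correlation, at adjusted p = 0.208 to adjusted p = 0.383. Of the drug's targets, PIM3 rose 1.37-fold, while PIM1 and PIM2 did not pass the test.

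Of 13009 tested genes, 3482 were called by edgeR, of which 1495 were higher in resistant cells and 1987 lower. Most changes were small, since the median absolute log2 fold change of called genes was 0.40 and 2320 of them changed by less than 1.5-fold. At least 2-fold changes were called for 631 genes, 103 higher and 528 lower. The 3 CPM values per group did not overlap for 5525 genes, or 42.5%, where chance alone gives 10%. The number of genes higher in resistant cells moved by over 1.5 times when a library was left out. It was 972 without resistant library 1, 922 without resistant library 2, 946 without resistant library 3 and 985 without naive library 3. Against a 1.5-fold change, 451 genes passed, 64 higher and 387 lower.

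**Figure D1:**
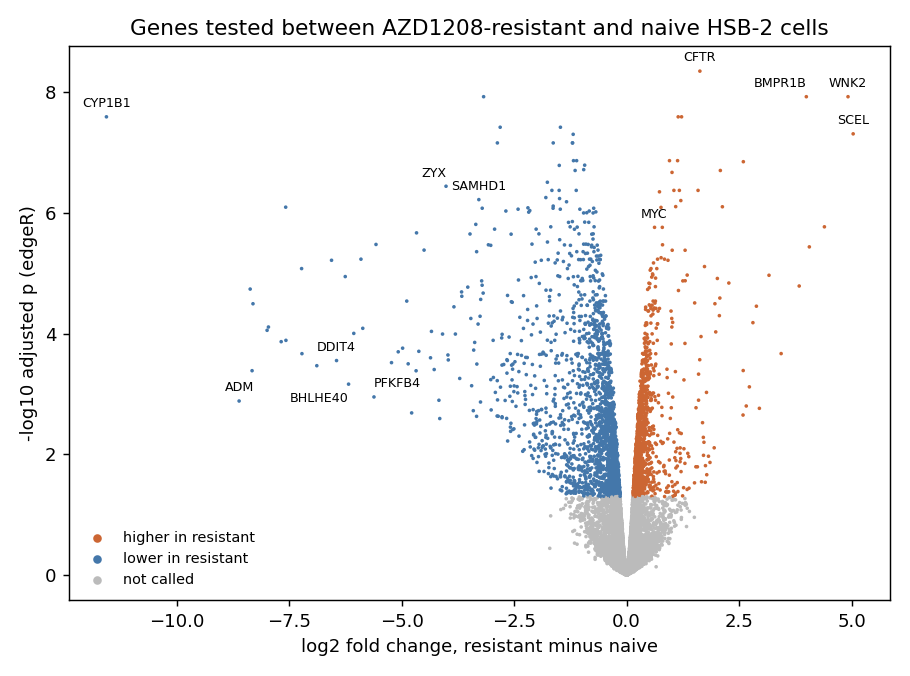
Log2 fold change, resistant minus naive, against minus log10 of the adjusted p from edgeR for the tested genes, with called genes in colour and 12 genes of the naming rule labelled; the position of CYP1B1, with 0 resistant counts, depends on the prior count. The 528 genes called at least 2-fold lower outnumber the 103 called at least 2-fold higher.

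The 3 largest rises under the naming rule, which asks for at least 5 CPM and no overlap, were in genes that naive cells barely expressed. SCEL (ENSG00000136155), known as a protein of the epithelial cornified envelope, had 12.2 ± 0.959 CPM in resistant cells and 0.380 ± 0.278 in naive cells (SD, n = 3 each), a log2 fold change of 5.03 (SE 0.26, adjusted p = 4.8e-08) that was 5.77 without naive library 3. WNK2 (ENSG00000165238), a kinase that regulates ion transport, had 10.9 ± 0.551 against 0.361 ± 0.150 CPM, a log2 fold change of 4.92 (SE 0.21, adjusted p = 1.2e-08). BMPR1B (ENSG00000138696), a receptor for bone morphogenetic proteins, had 13.6 ± 1.42 against 0.853 ± 0.16 CPM, a log2 fold change of 3.99 (SE 0.17, adjusted p = 1.2e-08). The most abundant of the 12 was CFTR (ENSG00000001626), a chloride channel of the ABC transporter family, which rose 3.09-fold from 91.5 ± 5.30 to 283 ± 10.2 CPM (adjusted p = 4.4e-09). The other 8 rose by log2 fold changes of 2.59 for MAT1A, 2.13 for GPA33, 2.08 for GPC1, 1.96 for ALDH3B2, 1.73 for PPEF1, 1.59 for GSE1, 1.51 for PIWIL4 and 1.35 for TNFRSF10A, a death receptor. GSE1 overlaps GINS2, PIWIL4 overlaps FUT4 and TNFRSF10A overlaps noncoding genes in the annotation, so part of their counts is uncertain.

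The 2 largest falls under that rule reached the limit of detection. CYP1B1 (ENSG00000138061), a cytochrome P450 enzyme, had 0 counts in each resistant library and 359, 393 and 258 in the naive ones, at least 137-fold lower with 3 counts allowed per library (adjusted p = 2.5e-08). ADM (ENSG00000148926), which encodes the vasodilator peptide adrenomedullin, had 0, 1 and 3 counts against 664, 241 and 462. Its naive to resistant ratio was 427 with a 95% exact interval of 167 to 1571 from counting (adjusted p = 0.0013). The fitted log2 fold change, which depends on the prior count, was -8.61 with and -9.68 without resistant library 3. DDIT4 (ENSG00000168209) fell from 49.2 ± 15.0 to 0.578 ± 0.290 CPM, a log2 fold change of -6.45 (SE 0.43, adjusted p = 0.00028). BHLHE40 (ENSG00000134107), a transcriptional repressor, fell from 45.1 ± 17.5 to 0.615 ± 0.157 CPM, a log2 fold change of -6.18 (SE 0.51, adjusted p = 0.00068). PFKFB4 had a log2 fold change of -5.61, ALDOC, a glycolytic aldolase, -4.78 and AK4, a mitochondrial adenylate kinase, -4.15. The call of AK4 was lost in limma-voom, with an adjusted p of 0.0558. ZYX had -4.01, CHST15 -3.67, EGLN3, an oxygen-sensing prolyl hydroxylase, -3.44, SAMHD1, a dNTP hydrolase, -3.28 and FGD5 -3.21. ZYX overlaps EPHA1, EGLN3 overlaps SPTSSA, ALDOC overlaps an unnamed gene and FGD5 overlaps its antisense gene, so part of their counts is uncertain.

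Hypoxia response genes fell as a group. Of 17 tested members, 15 fell and 1 rose, with the same numbers when adjusted over the list alone, and the median log2 fold change was -1.40 (camera adjusted p = 3.2e-08, adjusted p = 0.355 with an estimated correlation). Besides ADM, PFKFB4 and EGLN3, these included BNIP3 at -2.66 and BNIP3L at -2.51, which act in the removal of mitochondria, and VEGFA, an angiogenic growth factor, at -1.16. Glycolysis genes fell in 20 of 22 cases and rose in 0, both over all genes and adjusted over the list alone. Their median was -1.01 (camera adjusted p = 2.2e-11, adjusted p = 0.355 with an estimated correlation). The glucose transporter SLC2A3 had -2.77, hexokinase HK1 -1.59, the enolase ENO1 -1.11 and LDHA -0.95, from 2535 ± 316 to 1308 ± 42.3 CPM. LDHB, at 0.01, and PFKM, at -0.02, did not pass. SLC2A1, PDK1, PFKFB4 and HK2 are in both lists, so the lists are not independent. In both lists naive library 2 lay closest to the resistant libraries, with a mean hypoxia score of 0.60 against 1.13 and 1.07 in the other naive libraries and -1.02 to -0.85 in the resistant ones.

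**Figure D2:**
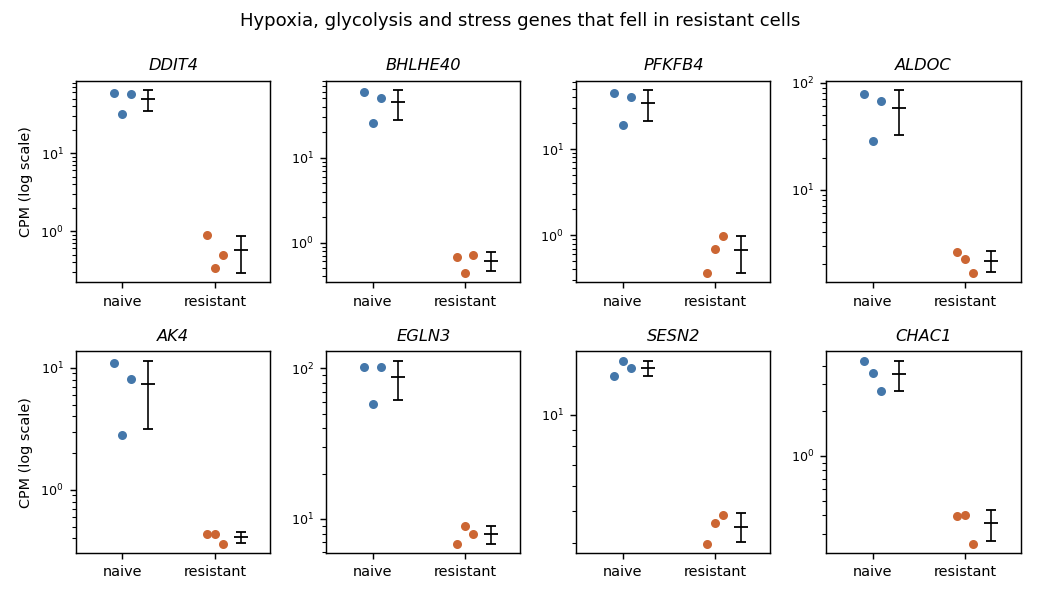
CPM on a log axis of 8 genes in each library, with points for the 3 naive and 3 resistant libraries and bars beside them for mean and SD. The genes are from the hypoxia, glycolysis and stress lists, except BHLHE40 and AK4, which are in none of the lists. All 3 resistant libraries lie below all 3 naive libraries for each gene, and DDIT4 has means of 49.2 and 0.578 CPM. For DDIT4, BHLHE40, PFKFB4, ALDOC, AK4 and EGLN3 the naming rule required this separation.

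Genes of the amino acid and stress response driven by ATF4 fell in 19 of 25 cases and 1 rose, with the same numbers adjusted over the list alone (camera adjusted p = 5.1e-09, adjusted p = 0.208 with an estimated correlation). CHAC1, a glutathione-degrading enzyme, had a log2 fold change of -3.33 (SE 0.30, adjusted p = 4.4e-06), the asparagine synthetase ASNS -1.50 and the cystine transporter SLC7A11 -1.18. ATF5 rose by 0.49 and overlaps NUP62. ATF4 itself, at -0.05, did not pass. The median log2 fold change of the list was -0.45, far from that of its member DDIT4. In naive libraries 1, 2 and 3 DDIT4 had 59.0, 32.0 and 56.7 CPM, lowest in naive library 2 as the hypoxia score was. The mean score of the ATF4 list, at 0.50, 0.54 and 0.58 in these libraries, was not lowest there. Of 24 p53 target genes, 12 fell and 3 rose, also when adjusted over the list alone (camera adjusted p = 0.0056, adjusted p = 0.355 with an estimated correlation). The cell cycle inhibitor CDKN1A had -1.38, SESN2, which also belongs to the ATF4 list, -1.63 and TP53INP1, which overlaps NDUFAF6, -1.54, while AEN rose by 0.54. Glucocorticoid receptor output genes fell in 8 of 12 cases and 1 rose, with the same numbers adjusted over the list alone (camera adjusted p = 0.0023, adjusted p = 0.391 with an estimated correlation). Of these, DDIT4, BIRC3 and TNFAIP3 are also in other lists, ZFP36, an mRNA decay factor, had -1.17 and the receptor gene NR3C1, at -0.11, did not pass.

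Of 18 NF-kB output genes, 12 fell and 0 rose, with 13 falling when adjusted over the list alone (camera adjusted p = 2.5e-07, adjusted p = 0.208 with an estimated correlation). TRAF1, a signalling adaptor, had a log2 fold change of -3.21 (SE 0.23, adjusted p = 8.3e-07) and the adhesion molecule ICAM1 -2.78. Interferon-stimulated genes fell in 13 of 27 cases and rose in 2, with 14 and 2 adjusted over the list alone (camera adjusted p = 0.0235, adjusted p = 0.383 with an estimated correlation, and 0.0536 with DESeq2 values). The antiviral OAS1 fell from 7.86 ± 1.54 to 3.92 ± 0.393 CPM and IFI35 had a log2 fold change of -0.86, whereas IFITM1 had 0.68. IFITM1 overlaps IFITM2, so part of its counts is uncertain. IFITM2, which is not in the list and was chosen after its value was seen, was called with -5.57. Of 23 chemokine receptor, integrin and adhesion genes, 15 fell and 4 rose, with 16 and 4 adjusted over the list alone (camera adjusted p = 4.8e-04, adjusted p = 0.29 with an estimated correlation). The chemokine receptor CCR4 had -1.86, the lymphocyte exit receptor S1PR1 -1.79, and the integrin chain ITGA4 rose by 0.76. Among natural killer and cytotoxic markers 2 of 4 fell and 0 rose, also when adjusted over the list alone. These were the granzyme GZMA at -1.26 and NKG7 at -0.73 (camera adjusted p = 0.0056, adjusted p = 0.29 with an estimated correlation, and 0.0601 without naive library 2).

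The PIM kinases, the targets of the drug, differed little in transcript level. PIM3 (ENSG00000198355) rose from 21.7 ± 2.82 to 29.8 ± 1.40 CPM, a log2 fold change of 0.45 (SE 0.09, adjusted p = 0.0029). PIM1 (ENSG00000137193) had 153 ± 3.83 CPM in resistant and 140.5 ± 7.74 in naive cells, a log2 fold change of 0.13 (SE 0.06, adjusted p = 0.11). PIM2 (ENSG00000102096) had 4.00 ± 0.0417 against 5.74 ± 1.81 CPM, a log2 fold change of -0.52 (SE 0.20, adjusted p = 0.071), and it was called without naive library 2 and without a filter on low counts. Of the 3 genes, 1 rose over all genes, and 2 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.459, fry adjusted p = 0.0203).

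MYC (ENSG00000136997) rose from 309 ± 5.10 to 476 ± 11.4 CPM, a log2 fold change of 0.62 (SE 0.05, adjusted p = 1.7e-06). Of 36 MYC target and ribosome biogenesis genes, 27 rose and 1 fell, with 29 and 1 adjusted over the list alone (camera adjusted p = 2.0e-10, adjusted p = 0.383 with an estimated correlation). Their median log2 fold change was 0.36, with 0.65 for the ribosome assembly factor RRS1 and 0.63 for the transferrin receptor gene TFRC. Naive library 2 lay closest to the resistant libraries here as well, with a mean score of -0.04. The other naive libraries had -0.24 and -0.19, and the resistant ones 0.13 to 0.18. The exception that fell was LDHA, which is also a glycolysis gene. Transcripts of the cytosolic ribosomal proteins did not move with them, since 0 of 40 were called in either direction, over all genes or adjusted over the list alone (camera adjusted p = 0.969). NOTCH1 rose by 0.37 (SE 0.06, adjusted p = 0.00087), HES1, a transcriptional repressor, by 1.01 and PTCRA, the pre-T-cell receptor alpha chain, by 1.02. Of 15 NOTCH pathway genes, 7 rose and 1 fell, with 7 and 2 adjusted over the list alone (camera adjusted p = 0.0219, adjusted p = 0.355 with an estimated correlation). The exception was TRIB2 at -0.38. The list was not called without naive library 2, with an adjusted p of 0.0727, or without a filter on low counts, with 0.116.

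**Figure D3:**
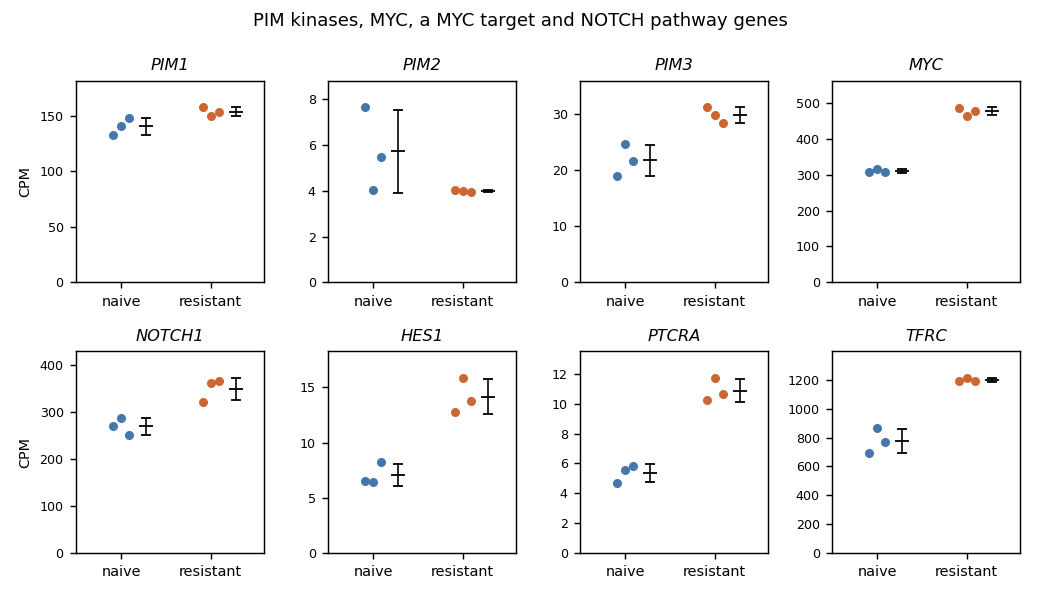
CPM from 0 of PIM1, PIM2, PIM3, MYC, NOTCH1, HES1, PTCRA and TFRC in each library, with points for libraries and bars beside them for mean and SD. MYC has means of 309 CPM in naive and 476 CPM in resistant cells, while the means of PIM1 are 140.5 and 153 CPM.

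Output genes of other growth pathways moved in both directions. Of 12 ERK pathway output genes, 5 fell and 1 rose, with 6 and 1 adjusted over the list alone (camera adjusted p = 0.0056, adjusted p = 0.29 with an estimated correlation). The early response gene EGR1 had a log2 fold change of -2.18 and the ERK phosphatase DUSP5 -2.15, while another ERK phosphatase, DUSP6, rose by 0.73. Of 19 STAT5 and cytokine signalling genes, 9 fell and 3 rose, also when adjusted over the list alone (camera adjusted p = 0.0334, adjusted p = 0.383 with an estimated correlation, and 0.0679 with a filter of 1 CPM). The interleukin-2 receptor chain IL2RA had -2.00, BCL6, a transcriptional repressor, -1.05, IL7R -0.33 (SE 0.05, adjusted p = 4.4e-04) and the cytokine OSM 1.09. Of 22 genes of mTORC1 signalling and cap-dependent translation, 2 rose and 2 fell, also when adjusted over the list alone (camera adjusted p = 0.248). EIF4EBP1, a repressor of translation initiation, had -0.66 and the kinase RPS6KA1 -0.36. Among 23 PI3K-AKT pathway genes 6 rose and 6 fell, with 7 and 6 adjusted over the list alone (camera adjusted p = 0.942). PIK3IP1, an inhibitor of PI3K, had -2.77, the transcription factor FOXO1 -0.82, the growth factor receptor IGF1R 0.48 and the phosphatase INPP5D 0.25. Of 10 receptor tyrosine kinases, 3 rose and 3 fell, also when adjusted over the list alone (camera adjusted p = 0.66), with 0.54 for FLT4 and -0.59 for TYRO3.

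Genes of T-cell identity moved in both directions. Of 27 T-cell receptor and proximal signalling genes, 6 rose and 11 fell, with 8 and 14 adjusted over the list alone (camera adjusted p = 0.12, fry adjusted p = 0.00455). The coreceptor CD4 rose by 0.71, the inhibitory receptor CD5 had -0.74 and the kinase TXK -0.87. LCK, the Src-family kinase next to the receptor, had -0.16 (SE 0.05, adjusted p = 0.042), with an adjusted p of up to 0.187 when a library was left out. Its call was also lost with median-of-ratios scaling (0.0561), DESeq2 (0.0703), no filter (0.092) and the replicate block (0.0991). Of 23 thymocyte differentiation factors, 8 rose and 5 fell, with 8 and 6 adjusted over the list alone (camera adjusted p = 0.444). The recombinase gene RAG1, which overlaps RAG2, rose by 0.64 and the transcription factor TCF7, which overlaps SKP1, by 0.50, while ID2 had -2.02 and RUNX3 -0.67. Of 8 early progenitor and T-cell leukaemia oncogene transcripts, 5 rose and 2 fell, also when adjusted over the list alone (camera adjusted p = 0.0425, adjusted p = 0.355 with an estimated correlation). These included MEF2C, a transcription factor, at 1.62, MYC at 0.62 and the adhesion receptor CD44 at -0.37. The list was not called without resistant library 1 (adjusted p = 0.269), 2 (adjusted p = 0.177) or 3 (adjusted p = 0.209) or without naive library 2 (adjusted p = 0.579). It was also lost with a replicate block (adjusted p = 0.0783), and its direction reversed without a filter on low counts (adjusted p = 0.977). TAL1, a T-cell leukaemia oncogene, was too low to test, with 0 counts in each resistant library and 10, 4 and 7 in the naive ones.

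Lists of ER chaperones and heat shock genes were called higher by camera. Of 21 ER chaperone and unfolded protein response genes, 8 rose and 3 fell, with 10 and 3 adjusted over the list alone (camera adjusted p = 0.0334, adjusted p = 0.485 with an estimated correlation, and 0.0696 without naive library 3). With a replicate block 6 members were called. The chaperone HSPA5 rose by 0.48 and HSP90B1, which overlaps UQCC6, by 0.40, and EDEM1, which targets misfolded proteins for degradation, had -0.62. Of 20 heat shock and proteasome genes, 7 rose and 1 fell, with 8 and 1 adjusted over the list alone (camera adjusted p = 0.0201, adjusted p = 0.625 with an estimated correlation). It was not called without naive library 1, with an adjusted p of 0.0501, or by fry, with 0.061. The heat shock gene HSPA1B, which shares sequence with its paralog HSPA1A, rose by 0.61, the cochaperone DNAJA1 rose by 0.43, and HSPA1A had -1.30. HSPA1A did not meet the naming rule, which asks for a call and at least 2 CPM.

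Lists of cell cycle, respiration, oxidative stress, cholesterol and autophagy genes were not called by camera, while fry called those of oxidative stress (adjusted p = 0.026) and autophagy (adjusted p = 0.00684). Of 26 S phase genes, 2 rose and 0 fell, also when adjusted over the list alone (camera adjusted p = 0.204), including UNG, a DNA repair enzyme, at 0.37, and 1 was called with a replicate block. Of 28 G2 and M phase genes, 2 rose and 4 fell, with 3 and 5 adjusted over the list alone (camera adjusted p = 0.66). NUSAP1, a spindle protein, had -0.27. Of 13 cell cycle inhibitors and G1 regulators, 3 rose and 3 fell, with 4 and 3 adjusted over the list alone (camera adjusted p = 0.757), and the kinase CDK6 rose by 0.69 and the cyclin CCND3 by 0.34. Of 43 oxidative phosphorylation genes, 2 rose and 1 fell, with 1 and 1 adjusted over the list alone (camera adjusted p = 0.248), including NDUFS6 at 0.26 and NDUFB5 at -0.28. Of 22 NRF2 and oxidative stress genes, 2 rose and 6 fell, with 3 and 8 adjusted over the list alone (camera adjusted p = 0.268), including the ferritin chain FTL at -0.60, and 5 were called with a replicate block. Cholesterol synthesis genes rose in 1 and fell in 4 of 24 cases, with 0 and 4 adjusted over the list alone (camera adjusted p = 0.447, and 0.0458 without naive library 1), including STARD4 at -0.55. Of 24 autophagy and lysosome genes, 0 rose and 7 fell, also when adjusted over the list alone (camera adjusted p = 0.0853). That list was called without naive library 1 (adjusted p = 0.0221), without resistant library 1 (adjusted p = 0.0485) and with DESeq2 values (adjusted p = 0.0469). GABARAPL1, an autophagosome protein, had -1.69 and WIPI1, which overlaps ARSG, -1.62.

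Of 11 BCL2 family genes, 2 rose and 3 fell, also when adjusted over the list alone (camera adjusted p = 0.581, fry adjusted p = 0.027), and 2 were called with a replicate block. The proapoptotic members BMF and BCL2L11 had log2 fold changes of -1.38 and -0.66. Of 8 tested genes of the ABC drug transporter list, 1 rose and 3 fell, also when adjusted over the list alone (camera adjusted p = 0.66). ABCC4 had 0.27 and ABCG1, a sterol exporter, -0.61. Those that fell include MVP, which encodes a vault protein and not an ABC transporter, so the falls are not a fall of drug efflux genes as such. Of 15 antigen presentation genes, 2 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 0.762), with 0.33 for the protease CTSS and 0.26 for CALR, a chaperone that is also in the ER list. Further called list members changed by less than 0.3 on the log2 scale and lost their call in at least 1 of the 6 fits that left out a library. These were EIF4E, EIF4G1, JAK2, NDUFB3, TXNRD1, GSR, EIF2AK3, SQLE, FDPS, BCL2L1, BID, TRIAP1, MCM7, CCNB1, CKS2, CDC25C, RBL2, FLI1, CXCR4, IRF1 and B2M, and MVP, at -0.56, lost its call as well. Their highest adjusted p in those fits lay between 0.0755 and 0.197. LDHA, BCL2L11, CDK6 and STARD4 overlap other tested genes in the annotation, so part of their counts is uncertain.

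Apart from the cytotoxic markers above, markers of other cell types were few. Of 4 tested B-lymphoid markers, 1 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 0.872), with 0.43 for the complement receptor CR2 and -2.16 for CD72. The mean of CD72 lay under the 2 CPM of the naming rule in both groups, so its fall rests on low counts. Too few members were counted well enough for a test in the lists of myeloid markers, with 0, of erythroid and megakaryocyte markers, with 0, and of stromal and epithelial markers, with 1, FN1, at 0.13. Of 15 mitochondrially encoded transcripts, 1 rose and 0 fell, also when adjusted over the list alone (camera adjusted p = 0.327, and 0.0221 without naive library 1), with 0.64 for MT-ND3. With a replicate block 7 of the 15 were called. Their mean scores were 0.23, 0.16 and -0.22 in resistant libraries 1, 2 and 3 and 0.33, -0.06 and -0.44 in naive libraries 1, 2 and 3. Of 11 histone and other transcripts without a poly(A) tail, 0 were called, also when adjusted over the list alone (camera adjusted p = 0.331).

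Of the 36 lists tested, camera called 16, with 5 higher and 11 lower, and none of these calls held with an estimated correlation. By fry, which does not compare a list with other genes, 20 were called, including 15 of the 16. The median and mean of a list had different signs for PI3K-AKT genes, ABC transporters, receptor tyrosine kinases, thymocyte factors, G1 regulators and antigen presentation genes. Lists called by camera numbered 13 without naive library 2 and 18 without naive library 1.

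**Figure D4:**
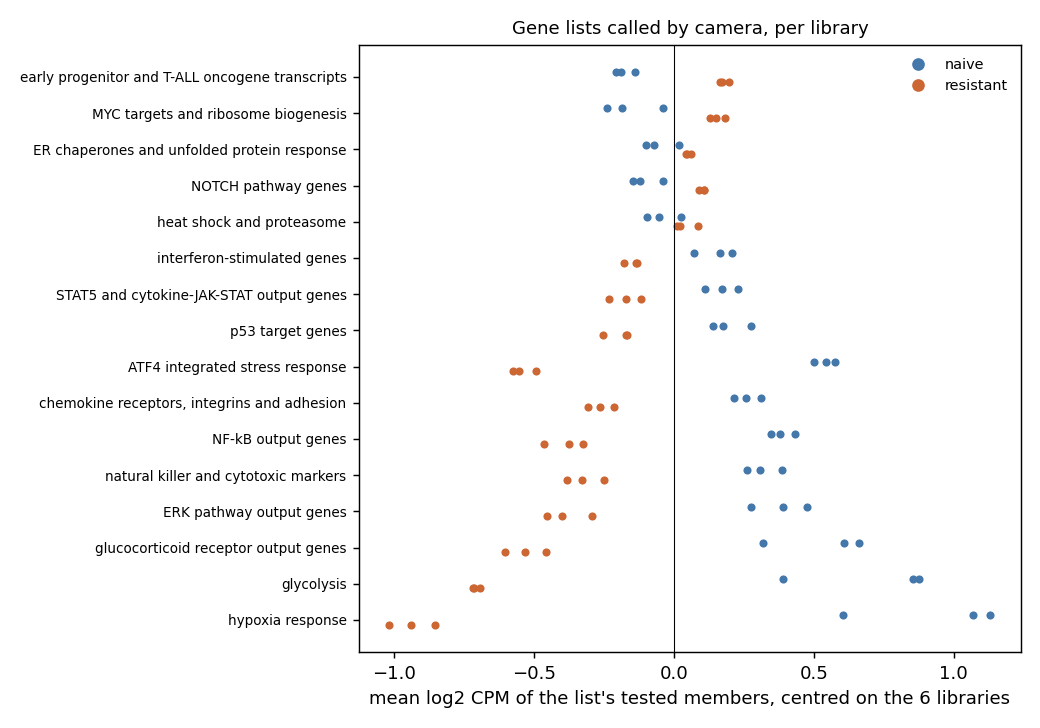
Mean log2 CPM of the tested members of each of the 16 called lists in each library, centred on the mean of the 6 libraries, with 1 point per library. The hypoxia list shows the widest separation, from -1.02 to -0.85 in resistant and from 0.60 to 1.13 in naive libraries, while the heat shock list overlaps between groups.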

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

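The test of this value was chosen only after the alignment summaries had been seen. The share of reads assigned to more than 1 place in the genome, which no comparison above uses, was higher in each resistant library than in any naive library. Resistant shares were 7.125% to 7.256% and naive shares 6.734% to 7.093%, so the gap between the groups was small beside the range of the naive libraries. Chance alone separates 3 libraries from 3 in 10% of cases. The share of reads assigned to more than 1 gene lay the other way, at 5.70% to 5.797% in resistant and 5.804% to 5.84% in naive libraries. No explanation was tested.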

How the results depend on the processing

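The alternatives were planned, except that the fit with the hypoxia score as a covariate was chosen only after the result was seen. Counts of called genes stayed within 1.5 times of 3482 under each other scaling, DESeq2, limma-voom, either filter and the replicate block (2951 genes, 2895 of them shared with the same sign). Leaving out 1 library gave 2346 to 4222 called genes, 922 to 1939 higher, 1424 to 2283 lower, 566 to 752 changed at least 2-fold and 13 to 18 lists. The count of higher genes was 972, 922 and 946 without resistant libraries 1, 2 and 3 and 985 without naive library 3. Against 1.5-fold, 451 genes passed, 64 higher and 387 lower, since that test asks for a larger change. With an estimated correlation between genes, 0 lists were called, against 16 with the preset one and 20 by fry. Of 125 tested named genes, 122 were called, a number largely fixed by the naming rule, which takes most genes only if they are called. Of these, 99 kept their call in all 6 fits that left out a library, while 16 lost it under another scaling, tool, filter or the block. Such fits share most libraries with the fit that chose the genes, so they are no independent support. Calls were lost by 21 without resistant library 1, 21 without resistant library 2, 19 without resistant library 3, 10, 3 and 21 without naive libraries 1, 2 and 3, and 15 with the block. The early progenitor list reversed without a filter on low counts, with an adjusted p of 0.977, and had 0.0783 with the block, over a range of 0.0783 to 0.977 among the alternatives that ended its call. The cause was not tested. Depth limits calls to genes with enough counts, as the simulated data showed for 2-fold changes.

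With the hypoxia score as a covariate, 4 genes were called, 2 higher and 2 lower, all 4 at least 2-fold, and 3 of them were shared with the comparison without it. The score had a correlation of -0.983 with the group, so standard errors grew 5.07 times at the median and the fit could not part the score from the group. Signs reversed, without a call, for ALDH3B2 (-1.26), ALDOC (0.22), AK4 (2.48), CHST15 (0.30), FGD5 (0.75), PIM3 (-0.68), EIF4E (-0.50), EIF4G1 (-0.28), PIK3IP1 (1.93), FOXO1 (0.83), OSM (-1.61), IL2RA (3.23), BCL6 (1.14), TRIB2 (0.32), RRS1 (-0.78), TFRC (-0.23), LDHA (0.043), NDUFS6 (-0.31), NDUFB3 (-0.34), TXNRD1 (-0.34), ATF5 (-0.24), HSPA5 (-0.64), HSP90B1 (-0.23), EDEM1 (0.25), EIF2AK3 (0.17), SQLE (-0.47), BCL2L1 (-0.56), BMF (2.43), BCL2L11 (0.27), ABCG1 (0.53), AEN (-0.86), TRIAP1 (-0.46), TP53INP1 (0.20), UNG (-0.19), CCNB1 (-0.89), CKS2 (-0.86), NUSAP1 (0.31), CDC25C (0.18), CCND3 (-0.23), RBL2 (0.79), TXK (0.99), CD5 (0.35), ID2 (1.71), RUNX3 (0.29), FLI1 (0.55), ZFP36 (0.43), OAS1 (0.61), CALR (-0.21), DNAJA1 (-0.26), WIPI1 (0.35), TYRO3 (0.76) and MT-ND3 (-0.18), as log2 fold changes.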

Other observations

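The genes in this part were chosen after their values were seen, the tests below followed patterns noticed in the same data, and the hypoxia score as a covariate and the test of neighbouring genes in its present form, over all genes changed at least 8-fold, were chosen only after the result was seen. Several signalling genes outside the lists differed by edgeR. BMP4, a bone morphogenetic protein and so a ligand of the receptor family of BMPR1B, rose from 13.3 ± 0.636 to 29.9 ± 0.183 CPM, a log2 fold change of 1.17 (SE 0.08, adjusted p = 4.2e-07). ANKRD1 rose from 141 ± 6.71 to 311 ± 9.20 CPM. The heparan sulfate enzyme NDST3 had a log2 fold change of 1.21, the small GTPase RHOU 1.22 and the nucleoside transporter SLC29A1 0.79. IGFBP2, an insulin-like growth factor binding protein, fell from 253.6 ± 79.7 to 34.7 ± 2.05 CPM, a log2 fold change of -2.87 (SE 0.28, adjusted p = 0.0013). The hexokinase-like gene HKDC1 had -3.18, and the transcription factors PRDM1 and KLF2 had -1.74 each. Among noncoding genes, MIR17HG, the host of a microRNA cluster, had 0.81, DANCR 0.78, LINC01120 2.07, NEAT1 -1.01 and LINC01819 -2.81. The pseudogenes BNIP3P1, at -2.29, and LDHAP4, at -0.81, moved with BNIP3, at -2.66, and LDHA, at -0.95, whose reads they can share.

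T-cell receptor V segments showed the same dominant segment in both groups, since TRBV29-1 had 337 to 381 CPM in all 6 libraries. Of 14 segments with at least 1 CPM in a library, 11 reached it in both groups, 3 in naive libraries only and 0 in resistant libraries only. The 3 were TRGV10, with 0, 0 and 0 against 33, 20 and 15 counts, TRBV5-1, with 0, 0 and 1 against 35, 37 and 34 counts, and TRAV30, with 13, 25 and 27 against 34, 39 and 26 counts, which lies near 1 CPM in both groups. The naive to resistant ratio of TRBV5-1 was 134, with a 95% exact interval of 23.6 to 5351 from counting. Grouped by chromosome, 0 of 23 chromosomes were called by camera, 0 had an unadjusted p under 0.05, the lowest being 0.104, and 0 were called with an estimated correlation. For the 79 genes called with at least an 8-fold change, the median log2 fold change of the 10 nearest tested genes, signed by the gene's own direction, was 0.0611 at the median and 0.375 at most. The median lies below 0.2, a bound set after the result was seen, so these genes as a set did not move with their neighbours. A gained or lost chromosome segment at some of them, or one too short to reach their neighbours, cannot be excluded by a median over the set.

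The 6 libraries can be split into groups of 3 in only 10 ways, so the share of splits giving as large a result cannot be under 0.1. The real split gave 3482 called genes, 1495 higher, 1987 lower and 631 at least 2-fold, and the highest of the other splits gave 0 for each. Each other split has libraries of both groups on both sides, so the group difference adds to the spread within a side. Few calls could therefore arise there, and the 0 does not measure the rate of false calls. For each of these counts 1 of the 10 splits, the real one, gave as many. For lists, 1 of the 10 gave as many, the real value being 16, the highest other 11 and the lowest other 3. Camera thus called lists in splits in which no gene was called. For chromosomes, 10 of the 10 gave as many, since the real value and the highest other were both 0.

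The lower hypoxia response and glycolysis transcripts in resistant cells are a pattern that technical causes were weighed against. The gap between the lowest naive and highest resistant library was 2.49 times the range of the naive libraries. That argues against the spread seen among these naive libraries as the source. No label says that they are separate cultures, so the spread between cultures may not be measured by it. The lists' median lay -1.12 from that of genes matched on abundance, length and GC content (35 genes), which argues against such bias. Under 3 other scalings the glycolysis median was -1.01 or lower, so it did not hinge on the choice among them. All of these scalings assume that most genes did not change, and the TMM factors were 0.985 to 1.013. They could therefore hardly differ, and they cannot show a change in total RNA per cell. A state shared by the naive cultures, such as density or oxygen, stays open, because the naive library was higher in 9 of 9 pairs and the labels give no density or day. A lasting change of the resistant population and an effect of drug present at harvest also stay open, as untested.

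The higher MYC target and ribosome biogenesis transcripts had a median 0.326 above that of genes matched on abundance, length and GC content, which argues against such bias. It was 0.372 above that of the cytosolic ribosomal proteins, which argues against a scaling shift. With the hypoxia score as a covariate, the median group coefficient became -1.01 times its value without it, which met the bound set for the score as the cause. That bound was set aside only after the result was seen. The covariate median of -0.36 had a member standard error of 0.29, and the score had a correlation of -0.983 with the group. The score and the group therefore cannot be told apart. The rise may therefore depend on the state that the hypoxia score measures or on resistance itself. It may also depend on anything else that differs between this resistant population and the naive cells, such as drug present at harvest. None of these was tested.

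The fall of CYP1B1 may reflect lower output of the aryl hydrocarbon receptor, which drives this gene. Of 4 other tested textbook targets of the receptor, 1 was called lower, CYP1A1, with 0 counts in each resistant library and 19, 27 and 36 in the naive ones (adjusted p = 7.7e-05). The log2 fold changes of AHRR (-0.41, adjusted p = 0.184), TIPARP (-0.28, adjusted p = 0.0769) and NQO1 (-0.50, adjusted p = 0.0544) did not pass in edgeR. The bound set beforehand against the hypothesis, too small a share of the tested targets called lower, was met with 1 of 4. It was set aside only after the result was seen, because it counted targets short of the threshold as unchanged. All 4 estimates lay below 0, but those that did not pass give little support, so the question stays open.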
